A study of Mus musculus with 4 samples.

How the data were processed

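Gene expression was measured in 4 samples of female mouse embryonic stem cells (ESCs), 2 of parthenogenetic haploid ESCs and 2 of parthenogenetic diploid ESCs. Parthenogenetic cells come from an unfertilised egg and carry only a maternal genome. Per the labels' protocols, total RNA was purified and 0.2 ug of it was amplified and labelled with Cy3, and each sample was hybridised to its own 1-colour Agilent array. All 4 arrays were on 1 slide and were scanned together, so slide and scan form no batch within the comparison. Each group holds samples numbered 1 and 2 that the labels assign to a line 1 and a line 2. The labels do not say that haploid line 1 and diploid line 1 share an origin, so samples of 1 number were not treated as pairs. Samples of a group were taken as separate experiments, as the series' design text states, and p-values measure the spread between these samples.

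Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 11.0.1.1, and the processed signal given there is a spot's intensity on a linear scale. The value table that the authors deposited beside them also holds linear intensity values. Its columns had medians of 28.4, 28.3, 28.4 and 28.3 for haploid replicates 1 and 2 and diploid replicates 1 and 2. They ranked the probes of each array nearly as the scanner values did (Spearman correlation across probes of 0.999867 to 0.999944), and their log2 values followed the log2 scanner signal (Pearson correlation across probes of 0.996 to 0.999), while the authors' way of bringing the 4 columns to 1 distribution is not given in the sources used here. The scanner files were the main source and the value table an alternative.

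The main values were log2 of the processed signal minus each array's 75th percentile of it. Control spots and spots marked as outliers were left out, which removed 121, 142, 126 and 168 of 43020 non-control spots from the arrays in the order above. Repeated spots of a probe were averaged. The 75th percentile of the signal was 526, 553, 617 and 907 intensity units, and 53.6%, 59.7%, 55.1% and 65.0% of probes were well above background. No spot was saturated. The number of arrays, not counting error, limits the precision.

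Of 39409 probes without outlier marks on all 4 arrays, 26043 (66.1%) were named by matching the accession in the scanner files to a table of RefSeq genes (assembly GRCm38.p6), giving 19748 symbols. The others kept their accession as an unnamed feature. Chromosome membership came from the same table, and no coordinate from it is given, since the array's design file names mm9. Probes had to be well above background on both arrays of at least 1 group, and the probe with the highest mean over all arrays stood for its gene. This left 17963 features, 13041 of them with a symbol. Among symbols, 3047 had over 1 probe past the filter, and for 1043 of these the probes differed in the sign of the difference.

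Haploid and diploid arrays were compared with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors are standard errors (SE) of the log2 difference from this fit, with n = 2 per group. Gene lists and chromosomes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists or over the chromosomes. Camera was also run with the correlation estimated for each list, and fry was run as a directional test. With the correlation estimated, camera rests on the fit's 2 residual degrees of freedom, so few lists could pass over 35 tests whatever their correlation. For the trophectoderm list, with an estimated correlation of -0.04, camera's unadjusted p rose from 1.5e-05 to 0.043. A call lost in this test therefore does not show that members vary together. A list needed at least 5 measured genes. Where a gene was not well above background on any array of a group, its difference is given as a bound. The bound sets the mean of the brighter group against the mean of the dimmer group's arrays, with each array's value raised to that array's lowest signal well above background where it lay below it. A p-value beside a bound tests the measured difference, not the bound. Dim probes can lie above an array's lowest signal well above background, so the bounds are not strict limits. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 read the files.

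The groups, the tests, the gene lists, 16 preset genes and the rule for naming genes were fixed before the data were examined. The rule took up to 12 genes with the largest and up to 12 with the smallest difference among called genes whose haploid and diploid values did not overlap, leaving out clone and predicted names. A direction with fewer than 6 such genes was filled up to 6 with the largest moderated t. It also took up to 4 members of each called list with the smallest p, the preset genes, and 6 members of the list of CDK1 control. Genes named outside the rule are said to be so.

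On simulated data with the real arrays' means and spread, in 10 runs with 200 changed genes among 17963, the fit recovered 10.6% of 2-fold, 87.8% of 4-fold, 97.2% of 8-fold and 99.2% of 16-fold changes. Of all calls in those runs 5.33% were false. Each gene's variance was drawn from the fit's own prior whatever its brightness, and no signal floor was set. These rates may thus not hold for dim features or for another number of changed genes. A list shifted by 0.5 on the log2 scale was called in 10 of 10 runs, with 1 false list call. The simulated genes varied independently, so these runs do not measure false list calls where members vary together. In the real data the estimated correlation was 0.96 for ribosomal protein genes and 0.45 for histone genes.

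Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, scaling to the median of probes well above background on all arrays, no filter, a filter on all 4 arrays, the value table, the mean of a gene's probes, a test of each probe, a prior variance with trend and robust fitting, the replicate number as a block, each array left out in turn and a 2-fold minimum. The mean signal column chosen for normexp is not among the columns used here, so the median signal took its place. Added after seeing the data were cyclic loess, values raised to a common floor, features with a symbol only, and 2 replacements for normexp, whose fit failed on diploid replicate 2. The first was plain background subtraction with the same offset and a net signal of at least 0.5, and after its result had been seen normexp without the spots whose local background exceeded 1000 was tried as well. Values given below for normexp on all spots come from the failed fit.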

Results

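The series asked how gene expression differs between haploid and diploid mouse ESCs, with the passage from G2 into mitosis as its stated theme. Haploid mouse ESCs tend to become diploid in culture. The data were 4 one-colour arrays, 2 of parthenogenetic haploid ESCs and 2 of parthenogenetic diploid ESCs. Over the 17963 features compared, signals correlated at 0.991 between the haploid arrays and 0.993 between the diploid arrays, and at 0.987 to 0.989 across groups (Pearson correlation across genes, which are not independent replicates). The median log2 difference of all features, haploid minus diploid, was 0.02.

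Few single genes passed the adjusted threshold, in a fit that recovered 10.6% of simulated 2-fold changes. Krt86, a type II hair keratin, was 4.60-fold higher in haploid cells (log2 difference 2.20 ± 0.21 SE, n = 2 per group, limma adjusted p = 0.0427). Ndst1, an enzyme of heparan sulfate synthesis, was 3.46-fold higher (1.79 ± 0.18, adjusted p = 0.0427), although its other probe differed by only 0.03. The other named genes that rose were not well above background on either diploid array. Btnl9, a butyrophilin-like gene, was at least 2.91-fold higher and Ugt2a3, a glucuronosyltransferase, at least 2.44-fold higher (adjusted p = 0.0392 for both). Oog3, of the oogenesin family of female germ cells, was at least 2.07-fold and Trim61 at least 1.82-fold higher, each at the same adjusted p, and Pate6 at least 1.64-fold higher (adjusted p = 0.0427). With normexp on all spots these 5 turned to -0.62 (Btnl9), -0.60 (Ugt2a3), -0.55 (Oog3), -0.65 (Trim61) and -0.80 (Pate6). That fit failed on diploid replicate 2, and all 5 kept their direction with normexp without spots of high local background. With values raised to a common floor they differed by 1.15 (Btnl9), 0.90 (Ugt2a3), 0.66 (Oog3), 0.47 (Trim61) and 0.32 (Pate6). The olfactory receptor genes Olfr435 and Olfr399 fell and were not well above background on either haploid array. Olfr435 was at least 3.47-fold lower (adjusted p = 0.0427) and Olfr399 at least 1.20-fold lower (adjusted p = 0.0451). With the common floor Olfr435 differed by -1.59 and Olfr399 by -0.05.

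In all, 20 features passed the test, 15 higher and 5 lower in haploid cells, of which 7 and 3 carried a gene symbol. The third lower symbol, the predicted gene Gm9871, was at least 2.79-fold lower (adjusted p = 0.0157) and is named after its value was seen. Of the 20, 6 were well above background on all 4 arrays and 13 were below it on both arrays of a group. The lower genes that came nearest the threshold did not pass it. Cxcl12, a chemokine, differed by -1.45 ± 0.19 (adjusted p = 0.0701). Htr5b, a serotonin receptor, Asah2, a ceramidase, and Bmper, a regulator of BMP signalling, had limma adjusted p of 0.0636, 0.0668 and 0.0707, with bounds of at least 1.26-fold, 2.22-fold and 1.27-fold lower. The number of calls depended on the processing: none remained with normexp on all spots, with cyclic loess, with values raised to a floor, without a filter or without diploid replicate 1. There were 2 with the replicate number as a block (0 higher, 2 lower), 5 with quantile normalization and 4 with the value table, while a prior variance with trend and robust fitting gave 425 calls (353 higher, 72 lower) and plain background subtraction 201 (188 higher, 13 lower). Without diploid replicate 2 there were 60 calls, 2 higher and 58 lower, of which 0 were among the 20. Without haploid replicate 1 there were 242 (235 higher, 7 lower) and without haploid replicate 2 there were 439 (334 higher, 105 lower).

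**Figure D1:**
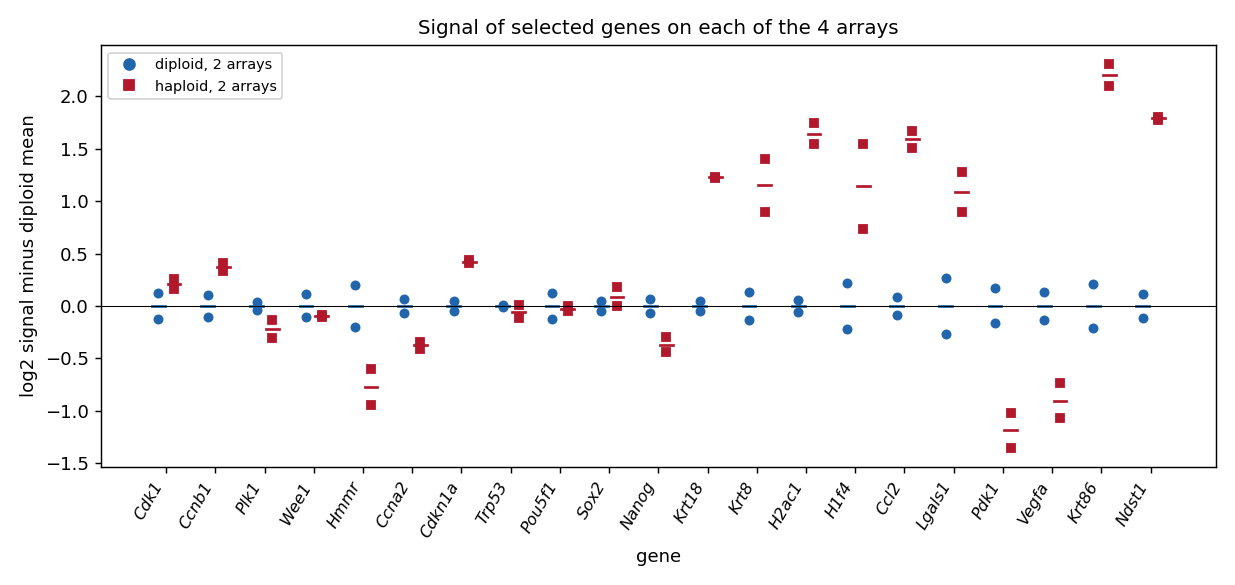
Signal of 21 named genes on each array, as log2 signal minus the diploid mean of that gene (vertical axis); circles are the 2 diploid arrays, squares the 2 haploid arrays, and short lines the group means. Krt86 and Ndst1 lay 2.20 and 1.79 above the diploid mean, while Pou5f1 and Trp53 differed by -0.03 and -0.06.

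No single gene of entry into mitosis passed the test. Cdk1, the kinase that starts mitosis, differed by 0.21 ± 0.18 (limma adjusted p = 0.657), with its other probes up to 0.61 and a range of 0.084 to 0.33 with 1 array left out, and its partner Ccnb1 (cyclin B1) by 0.37 ± 0.17 (adjusted p = 0.468), with its other probes as low as -0.19. Wee1, which holds CDK1 inactive, differed by -0.09 ± 0.18, Cdc25c, which activates it, by -0.13 ± 0.24, and the mitotic kinase Plk1 by -0.22 ± 0.17. As a list, CDK1 control and mitotic entry was lower in haploid cells, with 21 of 30 members below 0, a median of -0.20 and camera adjusted p = 0.0157. The list was not called with an estimated correlation (camera adjusted p = 0.829), a test that few lists could pass with 2 residual degrees of freedom. No member passed, adjusted over the list alone or over all genes. Hmmr, a spindle protein, differed by -0.77 ± 0.22, the spindle motor Kif11 by -0.50 ± 0.18, the checkpoint kinase Chek1 by -0.47 ± 0.18, cyclin A2 (Ccna2) by -0.38 ± 0.17 and the phosphatase Cdc25a by -0.37 ± 0.17 (adjusted p from 0.265 to 0.457). The list's median ran from -0.25 to -0.13 under the other scalings and background corrections, except for 0.05 with normexp on all spots, and its call ended without haploid replicate 1 (median -0.15) and without either diploid replicate (-0.26 and -0.12).

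Centrosome duplication and DNA damage repair were also lower in haploid cells by camera. For centrosome duplication, 15 of 18 members were below 0 and the median was -0.25 (adjusted p = 0.00315, and adjusted p = 0.829 with an estimated correlation). Cep152, a scaffold for new centrioles, differed by -0.89 ± 0.24, Cep57 by -0.40 ± 0.18, Cenpj by -0.32 ± 0.17 and Cep135 by -0.40 ± 0.22 (-0.60 to -0.20 with 1 array left out). In DNA damage repair, 23 of 30 members were below 0 and the median was -0.08 (adjusted p = 0.0226, and adjusted p = 0.829 with an estimated correlation), or 0.12 with normexp on all spots. Brca1 differed by -0.77 ± 0.30 (-1.17 to -0.36 with 1 array left out), the kinase Atm by -0.62 ± 0.20, Xrcc2 by -0.59 ± 0.19 (other probe -0.10) and Bard1 by -0.47 ± 0.18 (other probes up to -0.11). Neither list had a member that passed, adjusted over the list alone or over all genes. Leaving out haploid replicate 2 or diploid replicate 1 ended both calls (centrosome medians -0.20 and -0.25, repair medians -0.13 and -0.05).

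Other cell cycle lists were not called. Spindle checkpoint and kinetochore genes had a median of -0.12 (30 measured, adjusted p = 0.109), or 0.17 with normexp on all spots, and were called lower in 5 of 19 other settings. Genes of anaphase and cytokinesis (25 measured) and of G1/S and DNA replication (41 measured) had medians of 0.05 and 0.07, or -0.08 and -0.07 with quantile normalization, while camera placed both lower than other genes (adjusted p = 0.564 and 0.876) and their means were -0.03 and 0.00. With normexp on all spots both were called higher (0.41 and 0.43). For p53 targets and CDK inhibitors the median was 0.10 (28 measured, adjusted p = 0.563). In that list the CDK inhibitor gene Cdkn1a differed by 0.42 ± 0.17 (adjusted p = 0.413), with its other probe at 1.30, and Trp53 itself differed by -0.06 ± 0.17. Apoptosis genes had a median of -0.02 (21 measured, adjusted p = 0.563). In none of these 5 lists did a member pass, adjusted over the list alone or over all genes.

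Replication-dependent histone genes formed the list with the smallest p. Of 38 measured histone genes, 37 were higher in haploid cells, with a median of 0.74 or 1.67-fold (camera adjusted p = 1.25e-10, and adjusted p = 0.829 with an estimated correlation). H2ac1 differed by 1.65 ± 0.18 (adjusted p = 0.0528), H2bu2 by 1.29 ± 0.28, and the linker histones H1f5 and H1f4 by 1.17 ± 0.31 and 1.14 ± 0.31 (0.71 to 1.63 and 0.74 to 1.55 with 1 array left out). No histone gene passed over all genes, and 10 were higher adjusted over the list alone. The histone median differed between replicates too, haploid replicate 2 lying 0.57 above haploid replicate 1 and diploid replicate 1 lying 0.43 above diploid replicate 2. It stayed above 0 in every setting, from 0.43 without haploid replicate 2 to 1.06 without haploid replicate 1.

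Genes for ribosomal proteins and oxidative phosphorylation were higher in haploid cells by a small, even amount. All but 1 of 57 ribosomal protein genes lay above 0 (median 0.33, camera adjusted p = 2.21e-07), and 51 of 54 oxidative phosphorylation genes did (median 0.24, adjusted p = 0.000484). For both lists adjusted p = 0.829 with an estimated correlation. Rpl9 differed by 0.43 ± 0.21, and Rps14 and Rpl37 by 0.41 ± 0.21 each. The respiratory chain genes Uqcrfs1, Ndufb10 and Sdhc differed by 0.40 ± 0.17, 0.41 ± 0.23 and 0.35 ± 0.19 (other probe of Sdhc 0.05), and the ATP synthase gene Atp5c1 by 0.40 ± 0.20. With 1 array left out Ndufb10 ran from 0.12 to 0.71, Sdhc from 0.18 to 0.49 and Atp5c1 from 0.22 to 0.59. No member of either list passed, adjusted over the list alone or over all genes. These are bright probes, and over all features the median difference rose from -0.17 in the dimmest of 10 brightness classes to 0.22 in the brightest. Diploid replicate 1 lay above diploid replicate 2 by 0.44 for ribosomal protein genes and 0.37 for oxidative phosphorylation genes. The ribosomal median was 0.11 without diploid replicate 2 and 0.56 without diploid replicate 1. Both calls ended with quantile normalization (medians -0.0092 and 0.05), the value table (-0.0039 and 0.06) and cyclic loess (0.05 and 0.06), and the oxidative phosphorylation call also without haploid replicate 1 (0.23) or diploid replicate 2 (0.03).

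Trophectoderm markers, which belong to the outer layer of the blastocyst, were higher in haploid cells. Of 17 measured markers 14 lay above 0, with a median of 0.50 or 1.41-fold (camera adjusted p = 0.000106, and adjusted p = 0.829 with an estimated correlation). The keratin genes Krt18 and Krt8 differed by 1.23 ± 0.17 (limma adjusted p = 0.0781) and 1.15 ± 0.23, the transcription factor gene Gata3 by 1.02 ± 0.19 and the homeobox gene Rhox6 by 0.86 ± 0.19. None passed over all genes, and 7 were higher adjusted over the list alone. The list's direction held in every setting, with medians from 0.19 to 0.80. With the preset correlation its call ended only with normexp on all spots, while fry's directional test did not call the list (adjusted p = 0.144). Fibroblast markers were higher beside it, with a median of 0.41, or -0.15 with normexp on all spots.

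Fibroblast genes, fixed as markers of the feeder cells on which ESCs can be grown, were higher in haploid cells together with actin and adhesion genes. In the fibroblast list 24 of 30 measured genes lay above 0 (median 0.41, camera adjusted p = 3.46e-05, and adjusted p = 0.829 with an estimated correlation), or -0.15 with normexp on all spots. The chemokine gene Ccl2 differed by 1.59 ± 0.18 (limma adjusted p = 0.0528), Thbs1 by 1.39 ± 0.26, Fbln5 by 1.03 ± 0.22, S100a4 by 2.27 ± 0.51 (1.43 to 3.11 with 1 array left out) and Col1a1, a collagen I chain, by 0.99 ± 0.31 (0.61 to 1.36). None passed over all genes, while 6 were higher and 1 lower adjusted over the list alone. Cdh11, the lower one, differed by -0.71 ± 0.18 and is named after its value was seen. Of 36 actin and adhesion genes, 30 lay above 0 (median 0.36, camera adjusted p = 1.03e-05, and adjusted p = 0.829 with an estimated correlation), and 2 of them belong to the fibroblast list too. Lgals1 differed by 1.09 ± 0.25, Myl9, a myosin light chain, by 0.85 ± 0.23, Tagln2 by 0.74 ± 0.17 (other probe 0.36) and the annexin gene Anxa3 by 0.69 ± 0.16, none of which passed, adjusted over the list alone or over all genes. With the preset correlation the actin list was called in every other setting, with medians from 0.21 to 0.46. Fry's directional test did not call it (adjusted p = 0.261).

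Interferon response genes were higher as a list, with 12 of 15 above 0 and a median of 0.33 (camera adjusted p = 0.0058, and adjusted p = 0.829 with an estimated correlation), beside the higher fibroblast markers. Cxcl10 differed by 1.45 ± 0.17 (limma adjusted p = 0.0581) and Usp18 by 1.14 ± 0.21. Oasl2, not well above background on either diploid array, was 2.93-fold higher under the rule for bounds (adjusted p = 0.172). Its value on diploid replicate 1 (-4.50) exceeded that array's lowest signal well above background (-4.60), so 2.93-fold is no strict limit. Without diploid replicate 2 Oasl2 differed by 1.11. In the other direction, Rsad2 differed by -1.11 ± 0.19 and was well above background on only 1 haploid array. None passed over all genes, and 4 were higher and 1 lower adjusted over the list alone. The call ended without a filter (median 0.18), with normexp on all spots (0.09), and without haploid replicate 1 (0.31) or diploid replicate 2 (0.10).

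Hypoxia response genes were lower in haploid cells, with 15 of 19 below 0 and a median of -0.48 (camera adjusted p = 0.000593, and adjusted p = 0.829 with an estimated correlation). Pdk1, a kinase that limits mitochondrial use of pyruvate, differed by -1.19 ± 0.21, the growth factor gene Vegfa by -0.90 ± 0.20, Adm by -1.40 ± 0.43 (-2.08 to -0.71 with 1 array left out) and the glucose transporter gene Slc2a3 by -0.59 ± 0.20. None passed over all genes, and 2 were lower adjusted over the list alone. Haploid replicate 1 carried much of the list's difference: the list lay 0.70 lower in it than in haploid replicate 2, and without it the median was 0.04 and the call ended, while Pdk1 and Vegfa still differed by -1.02 and -0.74. It also ended without diploid replicate 1 (-0.27) and with normexp on all spots (-0.46).

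No preset marker of ESC identity passed the test. Pou5f1 and Sox2, core pluripotency factors, differed by -0.03 ± 0.18 and 0.09 ± 0.17, Nanog by -0.37 ± 0.17 and Zfp42, a marker of undifferentiated cells, by 0.33 ± 0.16 (limma adjusted p from 0.468 to 0.958). Core pluripotency genes had a median of -0.04 (20 measured, camera adjusted p = 0.255) and naive pluripotency genes one of 0.01 (25 measured, adjusted p = 0.997), or -0.07 with quantile normalization, and 0.36 and called higher with normexp on all spots. The core list was called lower in 4 of 19 other settings, with medians from -0.33 without haploid replicate 1 to -0.066, and called higher with normexp on all spots (0.28). Primed epiblast genes had a median of -0.01 (20 measured, adjusted p = 0.564), with 2 higher and 2 lower adjusted over the list alone and none over all genes. Genes of the 2-cell-stage-like state had a median of -0.15 (17 measured, adjusted p = 0.17) and were called lower without diploid replicate 2 (-0.23).

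Other lineage and germ cell lists were not called either. Medians were 0.09 for primitive endoderm (18 measured, camera adjusted p = 0.564), 0.27 for mesendoderm and mesoderm (15 measured, adjusted p = 0.648) and 0.02 for neuroectoderm (16 measured, adjusted p = 0.680). The mesendoderm and mesoderm median ran from 0.07 to 0.35 with 1 array left out. Gata4, a primitive endoderm factor well above background on only 1 haploid array, differed by -0.77 ± 0.28 (-1.12 to -0.43 with 1 array left out). Germline genes that respond to DNA methylation had a median of 0.20 (26 measured, adjusted p = 0.109), with 1 higher adjusted over the list alone and none over all genes. This list was called higher without haploid replicate 1 (0.36), while its median was 0.02 without haploid replicate 2. Oocyte genes had a median of -0.04 but a mean of 0.20, and camera placed them higher (14 measured, adjusted p = 0.876). Oog3 was the member called over all genes, and adjusted over the list alone 1 was higher and 2 were lower.

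Of the remaining lists on metabolism, stress and signalling, none was called in the main setting. Medians were -0.05 for glycolysis (21 measured, camera adjusted p = 0.564), -0.13 for cholesterol synthesis (24 measured, adjusted p = 0.0739), 0.22 for heat shock (17 measured, adjusted p = 0.0915) and 0.05 for the unfolded protein and integrated stress response (29 measured, adjusted p = 0.876), the last being -0.08 with quantile normalization. They were 0.13 for immediate early genes (20 measured, adjusted p = 0.564), -0.10 for MAPK feedback (20 measured, adjusted p = 0.538) and -0.04 for DNA methylation and demethylation (21 measured, adjusted p = 0.680). No member of these 7 lists passed, adjusted over the list alone or over all genes. Cholesterol synthesis was called lower in 8 of 19 other settings, at medians between -0.17 and -0.11. Glycolysis was called lower in 3 of 19 other settings, and with normexp on all spots glycolysis, heat shock and the stress response were called higher (0.33, 0.51 and 0.38).

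Imprinted genes were examined because the cells lack a paternal genome. Genes expressed from the maternal allele had a median of 0.04, or -0.10 with normexp on all spots, and a mean of -0.01, and camera placed them lower (21 measured, adjusted p = 0.690). Genes expressed from the paternal allele had a median of 0.25 (29 measured, adjusted p = 0.201) and were called higher without diploid replicate 2 (0.13). Adjusted over the list alone, 2 were higher and 2 lower among the maternal and 2 higher among the paternal genes, with none over all genes. Igf2 was not well above background on any array, and no probe was matched to H19.

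The X chromosome and the other chromosomes were compared as gene sets, and camera called none. The 498 genes of the X had a median of 0.11 (p = 0.00783, adjusted p = 0.157, and adjusted p = 0.778 with an estimated correlation). The X was called with the value table (median 0.09, adjusted p = 0.0498) and without haploid replicate 1 (0.22, adjusted p = 0.0361), and over all settings its adjusted p ran from 0.0361 to 0.969. Medians of the autosomes lay between -0.03 and 0.04. Xist, the RNA that silences an X chromosome, was not well above background on any array, and genes of the X inactivation centre had a median of -0.05 (6 measured, adjusted p = 0.876).

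**Figure D2:**
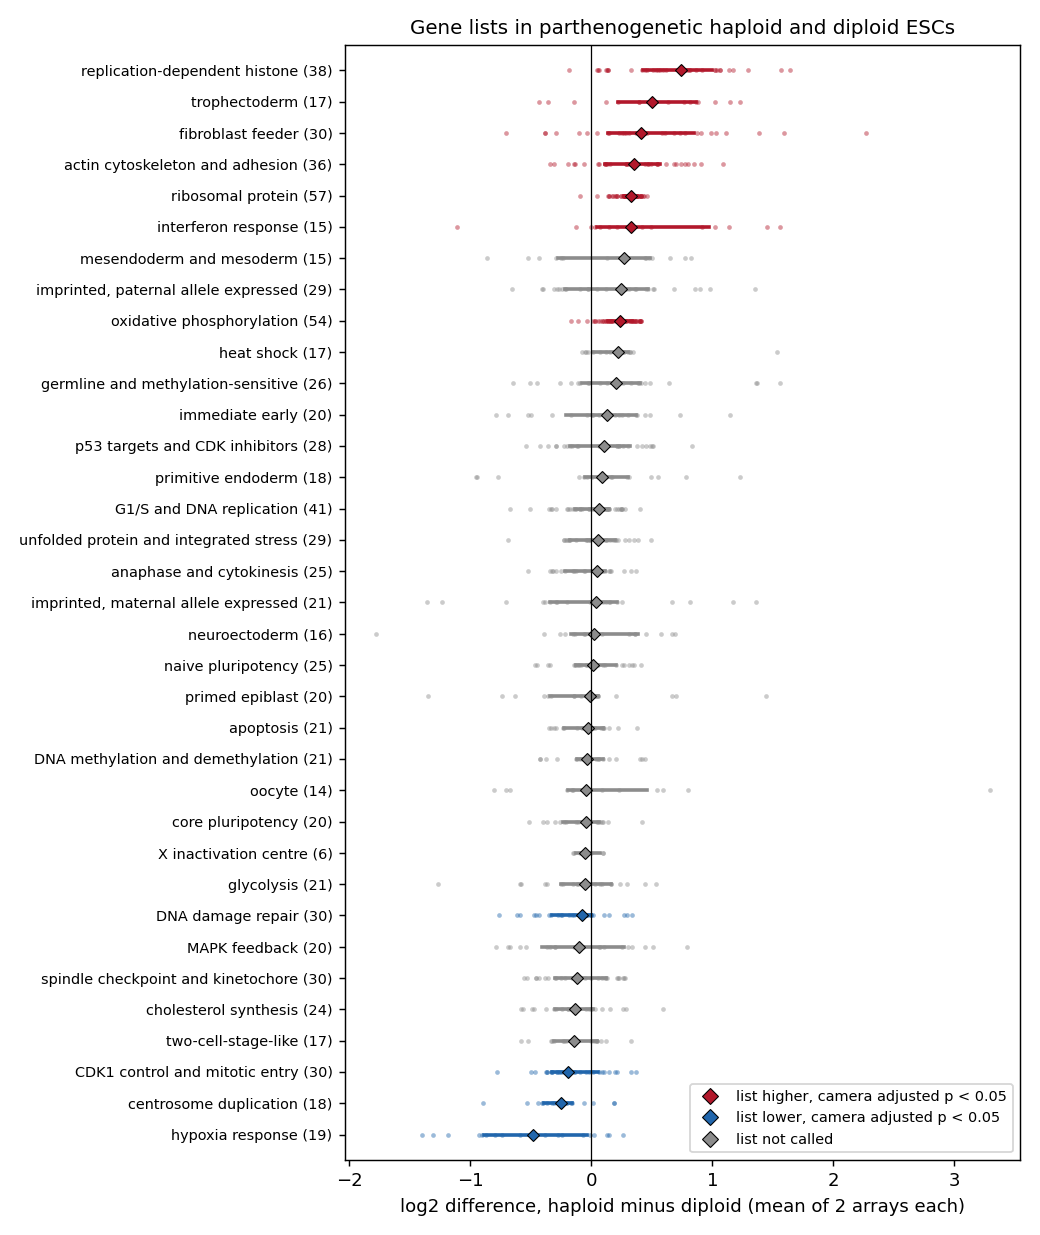
Log2 difference, haploid minus diploid, of the members of the 35 gene lists (horizontal axis, mean of 2 arrays each; the number measured in brackets); dots are genes, bars the quartiles and diamonds the medians, red for lists called higher, blue for lists called lower and grey for lists not called by camera with its preset correlation. Medians ran from -0.48 for hypoxia response to 0.74 for replication-dependent histone genes. With quantile normalization the ribosomal protein median was -0.0092. With normexp on all spots, whose fit failed on diploid replicate 2, the fibroblast, CDK1 and DNA damage repair medians changed sign.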

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

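Cyclic loess, the floor, the restriction to features with a symbol, background subtraction and normexp without spots of high local background were chosen after seeing the data, the last of these after the result of background subtraction had been seen. The 20 calls of the main setting (15 higher, 5 lower) became 0 with normexp on all spots, without a filter, with cyclic loess and with the floor, where unadjusted p stayed under 0.05 for 121, 1660, 2286 and 2068 features (limma). There were 5 calls (4 and 1) with quantile normalization, 4 (3 and 1) with the value table, 82 (78 and 4) with probes well above background on all 4 arrays, 35 (28 and 7) with each probe tested, and 425 (353 and 72) with trend and robust fitting. Normexp without spots of high local background gave 68 (66 and 2), background subtraction 201 (188 and 13), and features with a symbol gave 23 (20 and 3). The cause was not tested except for normexp. Leaving out 1 array, where the lone array is assumed to vary like the other group, gave 0 to 439 calls, 0 to 334 higher and 0 to 105 lower, 7 to 10 lists and 0 to 1 chromosomes. Without diploid replicate 2 most calls were lower (2 higher, 58 lower) and 0 were among the main 20. All 20 calls kept their direction in every setting that tested them except normexp on all spots, where 12 did. Their values did not overlap between groups, so leaving out 1 array could not turn the sign of a called probe. The kept direction is therefore no separate support. The scaling median and the 2-fold minimum changed no call.

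Replicate numbers did not pair the samples by their deviations from the group means (correlation 0.05 across genes). With the replicate block there were 2 calls, 0 higher and 2 lower, and 11 lists and 0 chromosomes as before. Camera with an estimated correlation called 0 lists, a test that few lists could pass with 2 residual degrees of freedom. Fry's directional p also called 0 lists, and other settings called 9 to 14, with 1 chromosome (X) with the value table.

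On diploid replicate 2, 7 spots had a local background over 1000 and drew its normexp fit off, raising its median corrected signal to 1277 against 107 to 116 on the other arrays; without them it was 168 and no called list changed direction. With them the median of all features moved from 0.02 to -0.10. Signs then turned for Btnl9 (-0.62), Oog3 (-0.55), Trim61 (-0.65), Pate6 (-0.80), Ugt2a3 (-0.60), Gata3 (-0.55), Fbln5 (-0.28), Anxa3 (-0.58), Cxcl10 (-0.0750), Usp18 (-0.32), Oasl2 (-0.60), Ccna2 (0.0021), Plk1 (0.19), Pou5f1 (0.40) and Cdc25a (0.0467). List medians turned for CDK1 control (0.0463), spindle checkpoint (0.17), DNA damage repair (0.12), core pluripotency (0.28), primitive endoderm (-0.41), mesendoderm (-0.75), neuroectoderm (-0.65), fibroblast (-0.15), paternally and maternally expressed imprinted genes (-0.20 and -0.10), DNA methylation (0.15), glycolysis (0.33) and cholesterol synthesis (0.0830). Calls ended for centrosome duplication (-0.28), trophectoderm (0.19), hypoxia (-0.46) and interferon response (0.0881).

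In other settings the ribosomal protein median turned to -0.0092 with quantile normalization and -0.0039 with the value table and its call ended with cyclic loess (0.0513). The oxidative phosphorylation call ended in these 3 settings (0.0523, 0.0575 and 0.0562). Without a filter the calls of DNA damage repair (-0.0789, adjusted p = 0.0516) and interferon response (0.18) ended. Uncalled medians also turned for G1/S (-0.0735 and -0.0790 with quantile normalization and the value table), heat shock (-0.0008 with the value table) and the X inactivation centre (0.0713 with cyclic loess, 0.0757 with background subtraction and 0.0663 with normexp without spots of high local background). With quantile normalization and the value table the small medians of anaphase and cytokinesis (-0.08 and -0.07), naive pluripotency (-0.07 and -0.06), the unfolded protein response (-0.08 and -0.07) and the X inactivation centre (0.01 in both) turned too. Further uncalled medians near 0 turned in other settings by less than 0.5 of their interquartile range and are not listed. Without 1 array, medians ran from -0.26 to -0.12 for CDK1 control, -0.31 to -0.20 for centrosome duplication, -0.13 to -0.0544 for DNA damage repair, -0.75 to 0.0361 for hypoxia, 0.0291 to 0.40 for oxidative phosphorylation and 0.10 to 0.43 for interferon response. They ran from -0.23 to 0.0908 for the 2-cell-stage-like list, -0.0757 to 0.11 for DNA methylation, -0.12 to 0.11 for the X inactivation centre, -0.14 to 0.22 for glycolysis and, as a difference, -0.39 to 0.13 for Cdc25c. Signal over background limits most single calls, since 13 of 20 rest on a group below background.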

Other observations

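Tests of feeder RNA and of the signal floor were chosen after the values they rest on had been seen, as were all genes named in the next 2 paragraphs. Near the threshold, 39 named genes were at least 2-fold higher and 2 at least 2-fold lower in haploid cells. They were well above background on all 4 arrays, did not overlap between groups and had limma adjusted p between 0.05 and 0.1. None of these passed the threshold. Some were list members already named above by the rule, such as H2ac1, Ccl2, Krt18 and Cxcl10. Lefty2, a Nodal antagonist, differed by 1.44 ± 0.20 and Cfc1, a Nodal co-receptor, by 1.79 ± 0.24 (adjusted p = 0.0781 for both), while Nodal itself differed by -0.08 ± 0.17, and no list of Nodal signalling was tested. The chemokine gene Ccl7 differed by 1.34 ± 0.17, in the direction of Ccl2 and Cxcl10 and against that of Cxcl12. The gamma-crystallin genes Crygd, Crygc and Cryga differed by 1.37 ± 0.18, 1.40 ± 0.19 and 1.16 ± 0.17. Cd3d and Cd3g, which encode CD3 subunits of the T cell receptor complex, differed by 1.46 ± 0.20 and 1.24 ± 0.17.

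The largest differences in this range were those of Pla2g2e (2.72 ± 0.33), Farp1 (2.72 ± 0.30), Isg20 (2.55 ± 0.28), Camk2a (2.54 ± 0.31) and Nrsn2 (2.47 ± 0.27). Each of these 5 genes was lower on diploid array 2 than on diploid array 1, and lower on both than on either haploid array. A further probe of Pla2g2e differed by -0.25 and one of Farp1 by 0.28, so these differences belong to single probes. Among imprinted genes, Plagl1, expressed from the paternal allele, differed by 1.36 ± 0.19 (adjusted p = 0.0848, other probes from -0.07 to 1.46) and Cdkn1c, expressed from the maternal allele, by 1.17 ± 0.17 (adjusted p = 0.0921). Of features well above background on all 4 arrays, 233 were at least 2-fold higher and 43 at least 2-fold lower in haploid cells without overlap, 276 in all. The other 2 ways of splitting the 4 arrays gave 51 each. Over all 17963 features, 47.0% did not overlap between haploid and diploid arrays, and 30.8% and 22.3% did not in the other splits. Chance alone leaves 33.3%. Features that passed the filter through 1 group only are among the 17963, which favours the haploid and diploid split. With 3 splits no share of splits can fall under 0.05.

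The histone, ribosomal protein and oxidative phosphorylation lists were higher in haploid cells on arrays whose differences rose with brightness and fell with gene span. For histone genes, the median residual from the brightness trend was 0.544 (95% bootstrap interval 0.47 to 0.71), and the list lay 0.541 above random lists matched on gene span and brightness, whose central 95% ended at 0.30, so both values argue against either trend as the whole cause. For ribosomal protein genes the residual was 0.0152 (-0.0057 to 0.034) and for oxidative phosphorylation genes 0.0418 (-0.019 to 0.078), so a brightness trend between arrays is a candidate explanation for both. The trend was fitted on all genes, those of the lists included. Bright list members thus helped to set it, and a small residual cannot decide the cause. Against random lists matched on gene span and brightness together, each in 10 classes, oxidative phosphorylation genes lay 0.0388 higher, inside the central 95%, and ribosomal protein genes 0.0604 higher, above it, a remainder that the fitted brightness trend did not leave. Why histone genes also differed between replicates of a group was not tested. A difference between haploid and diploid cells, such as in the share of cells in S phase, stays open and was not tested either. The list of G1/S and DNA replication was not called (median 0.07, camera adjusted p = 0.876).

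More RNA from feeder cells in the haploid samples is a candidate source of the higher fibroblast list, although the labels do not say whether these cells were grown on feeders, and neither test decided it. Of 5 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty and Usp9y), 0 were well above background on any array. How large a share of male feeders would have raised them above it was not tested, and feeders without male cells would not show. In the list, 5 of 30 members had 95% intervals wholly below its median of 0.41. All 5 differed below 0: Cdh11 by -0.71, Col3a1 by -0.39, Dcn by -0.38, Col6a2 by -0.11 and Mmp2 by -0.04. Since 29 of the 30 were well above background on both diploid arrays, a high baseline would hide a small feeder share in members near 0. The intervals of Col3a1, Dcn, Col6a2 and Mmp2 include 0. A hidden share gives no account of values below 0, and Cdh11's 95% interval (-1.15 to -0.26) lies wholly there. More feeder RNA and a difference of the haploid cells themselves therefore cannot be told apart.

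Called genes were dim, with a median log2 signal of -5.00 against -0.36 for all features tested. Differences made at the floor of the scanner signal would vanish once values below a common floor (-4.60 on the scaled log2 axis) were raised to it. The floor left 6 of the 20 calls unchanged, among them Krt86 and Ndst1, and of the 13 below background on both arrays of a group 8 kept at least a 1.5-fold difference in the same direction, among them Btnl9 and Olfr435 (15 of all 20, the set first counted). That number lies between the bounds set for either reading, so for these 13 a floor effect and true differences of weakly expressed genes cannot be told apart. No call passed the threshold with the floor (smallest adjusted p = 0.0508, over all settings 1.57e-05 to 0.873), and the cause was not tested.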
